A study of Homo sapiens with 36 samples.

How the data were processed

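Whole blood was collected in tubes with a stabilizing reagent and RNA was extracted with a kit for such tubes, per the labels. Stranded poly(A) libraries were sequenced with single-end reads of 100 bases to an average of 48.8 M reads, per the labels' protocols. The submitters' processing notes name FastQC, STAR, Subread, featureCounts and the human build hg38, without versions and without the role of each. Normalization, filtering and the log base are not given in the sources used here. The deposited table holds 1 column for each of 36 libraries and 11530 genes with symbols only. The deposited values are read as log2: as log2 the columns sum to 31.4 to 33.5 M on the linear scale, near the depth in the labels, which natural log or log10 values would far exceed.

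The values themselves show more of what the authors did. The 36 columns have nearly the same distribution, and the highest value is shared by 34 of 36 libraries, as after quantile normalization before genes were filtered. The mean of each gene over the 18 libraries with one form of title code equals its mean over the 18 with the other form, to within 3.4e-14 log2 for all 11530 genes, and no gene exceeded a tolerance of 1e-09. Differences in mean between those 2 sets of libraries, technical or biological, are thus gone from the table. HBB has 2 distinct values over the 36 libraries, HBA2 has 2 and HBA1 has 5, against a median of 36 distinct values per gene. No counts or depths are kept, so the depth behind a value is unknown and no counting interval is given. Errors are SDs or SEs over libraries.

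Before any test, 29 genes were removed because the libraries come from people: XIST and TSIX, genes of the male-specific part of the Y chromosome, HLA and KIR genes, variable segments of immunoglobulin and T cell receptor loci, and genes known to follow common inherited deletions or variants. The 11501 other genes were tested, with no filter on low values. There are 33 gene lists with 459 entries (markers of blood cell types, response programmes and signs of sample handling), fixed before the data were examined, as were the tests and the rule for named genes. Of the entries, 413 were measured, 14 of them under an older symbol, matched through RefSeq synonyms that belong to a single gene. Lists with at least 4 measured members were tested, which gave 32 lists, 19 of them of cell types. The 33 lists cover neutrophils, classical and non-classical monocytes, B cells, plasmablasts, T cells, naive T cells, CD8 T cells, NK and cytotoxic cells, regulatory T cells, MAIT cells, gamma delta T cells, eosinophils, basophils, plasmacytoid and conventional dendritic cells, platelets, erythroid cells, immature granulocytes, progenitors, type I interferon, interferon gamma, proliferation, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, heat shock, NF-kB targets, glucocorticoid response, clock, histones and cholesterol synthesis. Many blood cell types share such genes, and the score of a list stands for the expression of its members, not for a cell count.

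A list's score in a library is the mean over members of the log2 value minus the gene's mean over libraries. Coherence is the median pairwise Pearson r of members, set against 10000 random lists of the same size drawn from 20 bins of mean expression without list members; the smallest share these can give is 0.0001. Score correlations used two-sided permutation tests with 100000 permutations, whose smallest p is 1e-05, with Benjamini-Hochberg adjustment within each family. They were repeated without the 2 libraries farthest from the median of the first measure. Genes were related to scores with limma (lmFit and eBayes with trend and robust), with the score scaled to SD 1, so that a slope is the log2 change per SD of the score. A member of the list was tested against the score of the other members. In fits that leave out 1 library, the members' own p came from Pearson's test instead. The threshold was an adjusted p of 0.05 throughout. Variable genes and principal components were computed on gene-centred values. Named genes are the 10 genes outside the list with the highest and the 5 with the lowest r with a score among those called, without unnamed loci, the 2 members of each list with the highest and the 2 with the lowest r with the score of the others, from which examples are given, and the 25 genes with the largest SD. GC content and length came from the longest GENCODE release 29 transcript of each gene, found for 11453 genes (99.6%) and for all 413 list members.

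Alternatives fixed in advance were leaving out the lowest 25% of genes by mean, quantile normalization of the 11501 genes again, removing the mean of each title code form or adding the form as a covariate, leaving out the 2 libraries with the lowest median correlation with the others, Spearman in place of Pearson correlation, scores from z-scores, the neutrophil score as a covariate (the erythroid score for the neutrophil result), each title code form alone, 200 or 1000 variable genes, random lists matched on mean and SD, and components of genes scaled to SD 1. A change of pseudocount does not apply to values deposited as log2. After the data were seen, 4 alternatives were added: removal of each library's trend on GC content (cubic spline), removal of trends on GC content and length, leaving out the 2 libraries farthest from the median of a score, and leaving out each library in turn.

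The limma step was tested on simulated values with the means and SDs of 11501 genes and noise drawn independently for each gene. For genes with a list score, it found 95 of 100 genes made to correlate with the score at 0.7 in size and 38 of 100 at 0.5, and called 9 of 11276 unrelated genes. For 18 libraries against 18, it found 77 of 100 genes that differed by 1.5 SD and 18 of 100 that differed by 1 SD. The coherence step called 10 of 10 simulated lists of 10 members with a shared factor (pairwise r of 0.3) and 0 of 40 without. Apart from what was planted, the simulated genes were independent of each other, unlike the deposited ones. Neither the rate of false calls nor that of detection in the deposited values can therefore be read from these tests. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and statmod 1.5.0.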

Results

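The data are 36 libraries of human whole blood poly(A) RNA. Each has its own sample code, and all are in 1 group. The series' design text sets cell type predictions from expression beside flow cytometry. The cytometry was not analysed here. The comparisons ask which cell type and programme genes differed together between libraries, and by how much. The deposited values cover 11530 genes on a log2 scale, from 2.01 to 22.24, and the median value of a library lay between 9.28 and 9.31. Across genes, pairs of libraries correlated with r of 0.917 to 0.989 (median 0.973). The depth of each library is unknown, since the deposited values keep no counts; the labels give an average of 48.8 M reads. The labels number the libraries as 36 subjects, so the p-values of limma and of the correlations between libraries measure the spread between subjects. Those of list coherence and of Fisher's test are over genes, which are not independent replicates. Gene symbols are those of the deposited table, and coordinates are from GENCODE release 29 on GRCh38, with start and end covering the whole gene.

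Sample codes in the titles have 2 forms, 18 libraries each, which were treated as a possible batch. No gene separated them: limma called 0 of 11501 genes at an adjusted p under 0.05, and 0 genes had an unadjusted p under 0.05. The largest difference between the mean values of a gene in the 2 sets of libraries was 3.4e-14 on the log2 scale over 11530 genes, so the deposited values hold no difference in mean between them. Relations between measures were still computed within each form, and those values stand beside the pooled ones. With equal gene means, a pooled relation of scores or components is made up of those within the 2 forms. The values within forms show how evenly a relation is spread over them, and are not replications of the pooled one. The main fits and permutations hold no term for the form, although the equal means use up a degree of freedom. Their p-values are therefore somewhat too small. With the form as a covariate, limma called fewer genes with every score. The counts were 168 in place of 224 (eosinophil), 883 in place of 994 (NK and cytotoxic) and 3876 in place of 4005 (B cell).

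The first question was which fixed marker lists varied together between libraries. Members of 28 of the 32 lists tested correlated with each other more than random lists matched on mean expression (10000 random lists per list, one-sided, Benjamini-Hochberg over 32 lists). Ribosomal protein genes were the most coherent, with a median pairwise r of 0.864 over 40 genes, followed by erythroid genes at 0.791 over 20 and type I interferon-stimulated genes at 0.778 over 25 (adjusted p = 0.000229 for each). Median r was 0.778 for 5 basophil genes, 0.764 for 18 platelet genes, 0.751 for 14 cell cycle genes, 0.746 for 6 plasmablast genes, 0.742 for 14 mature neutrophil genes and 0.708 for 16 B cell genes. It was also 0.734 for 25 nuclear oxidative phosphorylation genes, 0.708 for 15 immature granulocyte genes, 0.699 for 12 mitochondrially encoded genes and 0.649 for 6 histone genes. The matched random lists had medians between -0.03 and 0.004. The T cell list reached 0.581, naive T cells 0.568, eosinophils 0.530, NK and cytotoxic cells 0.480, plasmacytoid dendritic cells 0.450 and classical monocytes 0.435. Interferon gamma-induced genes reached 0.427, non-classical monocytes 0.388, inflammatory NF-kB targets 0.348, heat shock genes 0.291 and immediate early genes 0.175. The list of 10 glucocorticoid-induced genes passed with an adjusted p of 0.0211. The weakest calls among cell lists were mucosal-associated invariant T (MAIT) cells at 0.414 (adjusted p = 0.0428), CD8 T cells at 0.282 (adjusted p = 0.0478) and regulatory T cells at 0.278 (adjusted p = 0.0428). These calls did not hold under every alternative. The adjusted p of the CD8 T list ran from 0.0244 to 0.103, that of the regulatory T list from 0.0277 to 0.157, and that of the MAIT list was 0.0974 in title code form 1 alone. The non-classical monocyte and plasmacytoid dendritic cell lists had adjusted p of 0.0957 and 0.0563 without the genes in the lowest 25% of mean values, and the heat shock list had 0.0974 in form 1 alone. The lists of cholesterol synthesis (median r 0.152), conventional dendritic cells (0.141), circadian clock genes (0.126) and haematopoietic progenitors (0.105) did not pass, with adjusted p of 0.0568, 0.0619, 0.0651 and 0.0687. With each library's trend of values on GC content removed, an alternative chosen after the data were seen, all 4 passed, with adjusted p between 0.0261 and 0.0354. The gamma delta T list had 1 measured member and was not tested.

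Members were also tested one by one against the score of the rest of their list, a score being the mean over members of the log2 value minus the gene's mean over libraries. All 25 interferon genes rose with the score of the others over all genes tested, as did all 20 erythroid, 40 ribosomal protein, 16 B cell, 14 T cell and 14 cell cycle genes (limma, adjusted p under 0.05), and the same members passed when adjusted over the list alone. RSAD2, which encodes the antiviral protein viperin, rose by 1.22 ± 0.03 (SE, n = 36) log2 per SD of the interferon score. CD22, a B cell inhibitory receptor, rose by 0.68 ± 0.04 per SD of the B cell score, PRF1, the pore-forming protein perforin, by 0.50 ± 0.03 per SD of the NK score, and SLC4A1, the red cell anion exchanger, by 0.97 ± 0.05 per SD of the erythroid score. CEACAM8, a granulocyte adhesion molecule, rose by 1.37 ± 0.07 per SD of the immature granulocyte score and TNFRSF17, the plasma cell receptor BCMA, by 1.07 ± 0.07 per SD of the plasmablast score. Of the neutrophil list, 13 of 14 members rose over all genes tested and 14 when adjusted over the list alone. The member outside the first count was S100P, a calcium-binding protein (0.75 ± 0.29 log2 per SD, adjusted p = 0.0519). Of the NK and cytotoxic list 15 of 16 rose over all genes, and 16 of 16 when adjusted over the list alone. The platelet list had 17 of 18 and 18 of 18 in the same order, the eosinophil list 9 and 11 of 11, the immature granulocyte list 14 and 15 of 15 and the classical monocyte list 9 and 11 of 12. No member of the regulatory T (6 genes), conventional dendritic cell (8), progenitor (7) or cholesterol (12) lists passed over all genes, and 3, 2, 1 and 4 did when adjusted over the list alone. FOXP3, the lineage factor of regulatory T cells, had a slope of 0.02 ± 0.08 log2 per SD of its list's score (limma, adjusted p = 0.908).

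The next question was how far each list moved between libraries. The immature granulocyte score had the widest spread, with an SD of 0.98 log2 over 36 libraries and a 5.69-fold difference between the 10th and the 90th percentile. The erythroid score followed with an SD of 0.79 (3.45-fold), then plasmablasts with 0.73 (3.18-fold), interferon with 0.71 (3.43-fold) and basophils with 0.62 (2.55-fold). Scores of cell cycle genes (SD 0.60), neutrophils (0.59), platelets (0.58), eosinophils (0.57) and B cells (0.56) spread over 2.18- to 2.77-fold between the same percentiles. The T cell score moved less, with an SD of 0.28 and a 1.62-fold difference, and the classical monocyte score had an SD of 0.27. The smallest SD was 0.12, for cholesterol synthesis genes. These spreads are in the authors' normalized scale, in which all libraries have nearly the same distribution of values.

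**Figure D1:**
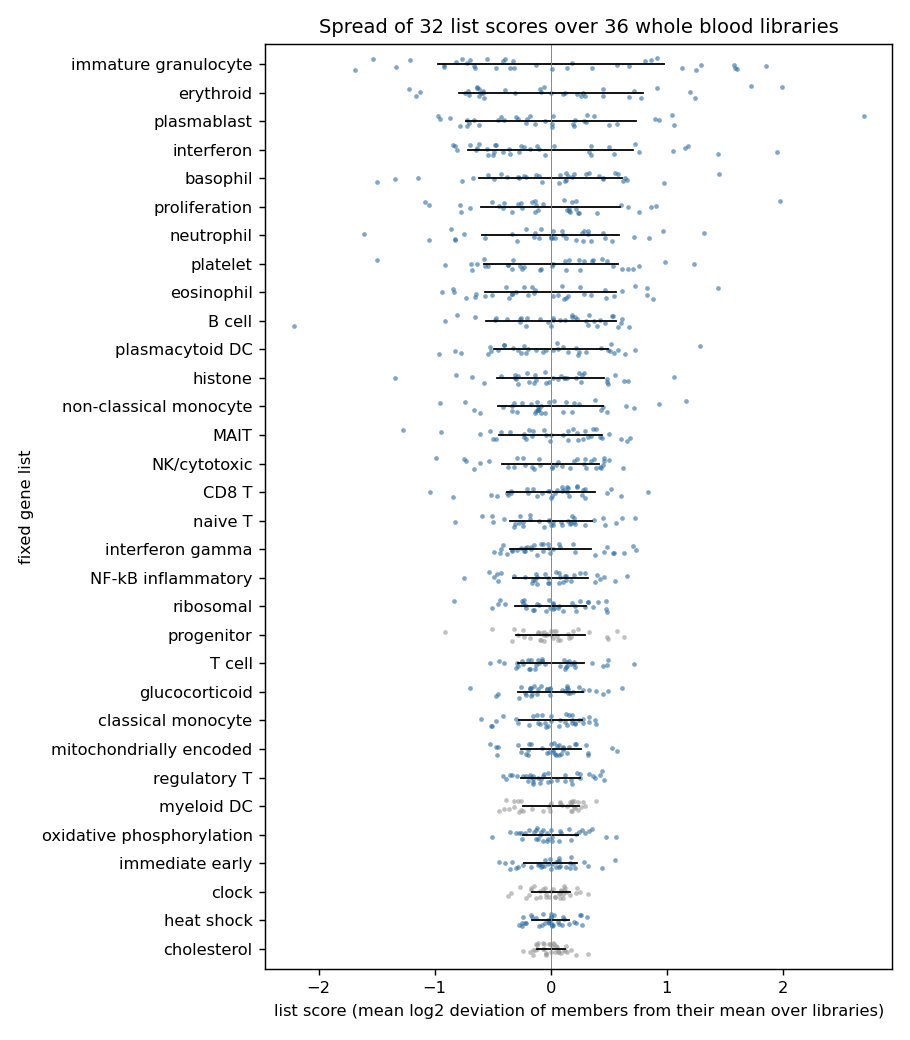
Each point is the score of 1 of 36 whole blood libraries for a fixed gene list, in log2 units around the list's mean, and the black bar spans 1 SD to each side. Lists are ordered by SD, from 0.98 for immature granulocytes at the top to 0.12 for cholesterol synthesis at the bottom, and grey points mark the 4 lists whose members were not more correlated than random lists.

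The relation between cell types was examined over all 171 pairs of the 19 cell lists with at least 4 measured members. The scores of 15 pairs were correlated at an adjusted p under 0.05 (two-sided permutation test, 100000 permutations, Benjamini-Hochberg over 171 pairs), 9 positively and 6 negatively. Libraries with higher neutrophil scores had lower CD8 T scores (r = -0.693, p = 2e-05, adjusted p = 0.000855; rho = -0.662, p = 3e-05), with r of -0.709 and -0.690 within the 2 title code forms. Without the 2 libraries farthest from the median neutrophil score, r was -0.582. The neutrophil score went down in the same way with the T cell score (r = -0.607, p = 2e-05, adjusted p = 0.000855; rho = -0.519, p = 0.00142; -0.645 and -0.629 within forms; -0.516 without 2 libraries). It also fell with the NK and cytotoxic score (r = -0.535, p = 0.00067, adjusted p = 0.0229; rho = -0.517, p = 0.00147; -0.559 and -0.504 within forms; -0.503 without 2 libraries). All libraries have nearly the same distribution of values, and cell types share 1 whole, so scores are relative. A negative relation between 2 scores thus does not show which of them changed in amount. The permutations, which take unrelated scores as their reference, do not allow for this. Platelet and erythroid scores rose together (r = 0.479, p = 0.00319, adjusted p = 0.0403; rho = 0.510, p = 0.00161; 0.368 and 0.546 within forms; 0.441 without 2 libraries). Eosinophil and basophil scores did so as well (r = 0.489, p = 0.00262, adjusted p = 0.039; rho = 0.481, p = 0.00318; 0.443 and 0.553 within forms; 0.396 without 2 libraries).

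The T cell score rose with the naive T score (r = 0.704) and the CD8 T score (r = 0.685), both at p = 1e-05, the smallest that the permutations can give, and adjusted p = 0.000855. Their rho were 0.669 (p = 1e-05) and 0.668 (p = 2e-05), r within forms 0.466 and 0.871 for naive T and 0.621 and 0.739 for CD8 T, and r without 2 libraries 0.613 and 0.623. Classical monocytes went against eosinophils (r = -0.493, p = 0.00232, adjusted p = 0.039; rho = -0.498, p = 0.00236; -0.533 and -0.464 within forms; -0.381 without 2 libraries) and basophils (r = -0.473, p = 0.0033, adjusted p = 0.0403; rho = -0.516, p = 0.0015; -0.354 and -0.614 within forms; -0.421 without 2 libraries). Of the other 6 pairs, non-classical monocytes went against naive T cells (r = -0.516), and CD8 T with NK cells (0.510), CD8 T with MAIT cells (0.514), NK with MAIT cells (0.488), MAIT cells with progenitors (0.490) and T cells with regulatory T cells (0.464) went together, with adjusted p between 0.0306 and 0.0494. For the negative pair rho was -0.580 (p = 0.00028), r within forms -0.410 and -0.600, and r without 2 libraries -0.513. For the 5 positive pairs rho lay between 0.338 and 0.488 (p between 0.00277 and 0.0431), r within forms between 0.329 and 0.691, and r without 2 libraries between 0.218 and 0.519. The progenitor list was not coherent, and none of its 7 members or of the 6 regulatory T members followed the rest of its list over all genes, so these 2 scores are means of genes that moved little together. The CD8 T list was also weakly coherent, with a median pairwise r of 0.282. Of its 7 members, 5 rose with the rest over all genes, while GZMK (r = 0.343) and CD160 (r = -0.065) did not. The CD8 T and MAIT relation rested on 2 libraries, without which r was 0.218. Leaving out the 2 libraries least like the others kept 5 of the 15 pairs, among them neutrophils with T and CD8 T cells, and with 18 libraries each, form 1 alone gave 0 pairs and form 2 alone gave 2. With GC content and length trends removed, 6 of the 15 pairs passed, among them the 3 of neutrophils. B cell, dendritic cell, plasmablast and immature granulocyte scores were in no called pair.

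**Figure D2:**
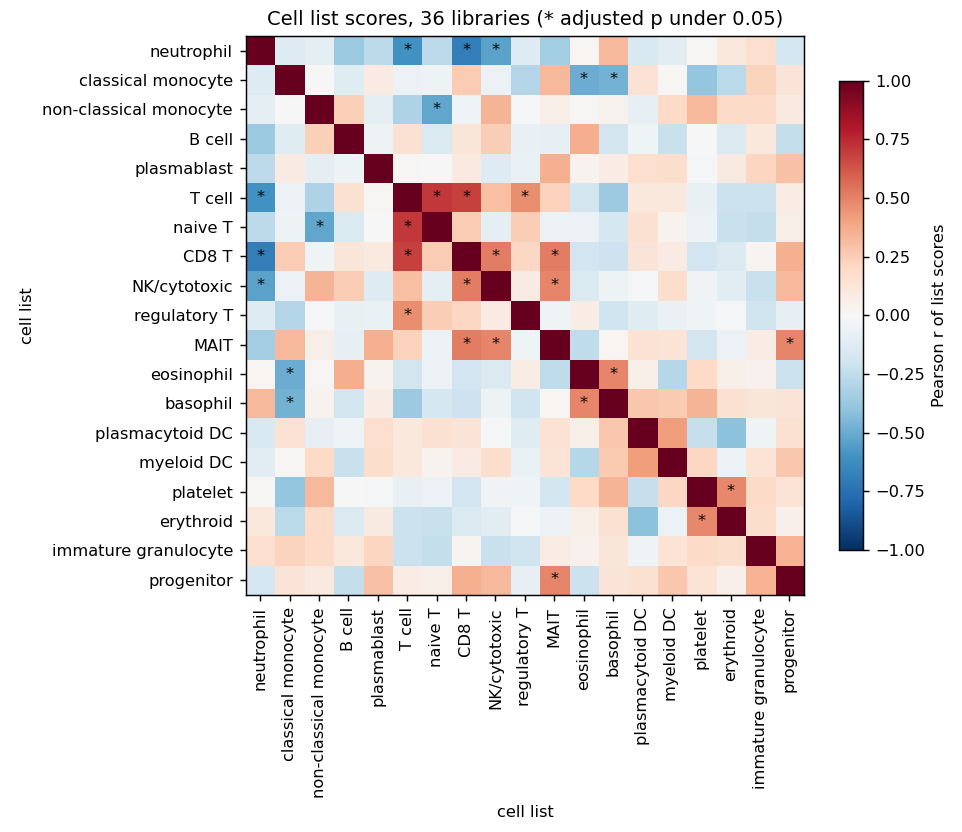
Colour gives the Pearson r between the scores of each pair of the 19 cell lists over 36 libraries, with both axes listing the same cell lists, and a star marks the 15 pairs with an adjusted p under 0.05. The neutrophil row holds the lowest r, -0.693 with CD8 T cells, and the T cell and naive T pair the highest, 0.704.

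The genes that moved with each of 8 scores were then counted among all genes outside the list (limma with trend and robust settings, Benjamini-Hochberg over 11501 genes). With the interferon score, 44 of 11476 genes changed, 41 upwards and 3 downwards. The strongest by correlation was IFIH1, the cytosolic RNA sensor MDA5 (chromosome 2, 162267079 to 162318703), which rose by 0.33 ± 0.03 (SE, n = 36) log2 per SD of the score (adjusted p = 1.21e-10). LAMP3, a lysosomal membrane protein of dendritic cells, rose by 0.62 ± 0.08, AGRN by 0.50 ± 0.07, PARP14 by 0.37 ± 0.04, IFIT5 by 0.35 ± 0.04, ZCCHC2 by 0.31 ± 0.04, DDX58, which encodes the RNA sensor RIG-I, by 0.28 ± 0.04, and STAT2, a signalling factor of the interferon receptor, by 0.27 ± 0.04. DTX3L rose by 0.23 ± 0.04 and TOR1B by 0.17 ± 0.03. The 3 genes that fell were ENTPD2 (-0.63 ± 0.14), TNFRSF9, the costimulatory receptor 4-1BB (-0.34 ± 0.08), and FAM101B (-0.18 ± 0.04). FAM101B was near the threshold (adjusted p = 0.0469) and missed it without the genes in the lowest 25% of mean values, with the form as a covariate and without the 2 libraries least like the others, with adjusted p of 0.0535 to 0.0580. With the neutrophil score as a covariate TNFRSF9 and FAM101B did not pass, without the 2 libraries farthest from the median score ENTPD2 and FAM101B did not, and in form 2 alone none of the 3 did. All 44 genes had the same direction within each title code form. This was close to fixed in advance, since they were called over the same libraries and the forms have equal gene means. The count was 75 with the neutrophil score as a covariate, 12 and 14 in the 2 forms alone, and 26 without the 2 libraries farthest from the median score, of which 24 were among the 44.

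With the neutrophil score, 3041 of 11487 genes changed, 1470 upwards and 1571 downwards. AQP9, a glycerol and water channel (chromosome 15, 58138169 to 58185911), rose by 0.58 ± 0.03 log2 per SD (adjusted p = 8.86e-16). LRRC4 rose by 0.63 ± 0.04, QPCT, glutaminyl cyclase, by 0.61 ± 0.04, MANSC1 by 0.60 ± 0.04, DYSF, the membrane repair protein dysferlin, by 0.58 ± 0.04, REPS2 and PPP1R3B by 0.55 ± 0.03 and 0.55 ± 0.04, PYGL, glycogen phosphorylase, by 0.48 ± 0.03, the transcription factor NFIL3 by 0.48 ± 0.03 and NDEL1 by 0.28 ± 0.02. The genes with the lowest correlations fell by less: AES by 0.26 ± 0.03, XRCC6, the DNA repair protein Ku70, by 0.22 ± 0.03, ATP5B, a subunit of ATP synthase, by 0.18 ± 0.02, the histone deacetylase HDAC1 by 0.12 ± 0.02 and the nuclear pore protein NUP93 by 0.11 ± 0.02. The counts in the 2 forms alone were 1257 and 1222, of which 1247 and 1169 were among the 3041.

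With the ribosomal protein score, 3913 of 11461 genes changed, 2163 upwards and 1750 downwards. Of the 10 named genes that rose, 8 encode ribosomal proteins outside the list, led by RPS16 (chromosome 19, 39433207 to 39435948; 0.33 ± 0.02 log2 per SD, adjusted p = 2.97e-18). RPS27A rose by 0.30 ± 0.02, RPL7A by 0.27 ± 0.02, RPL13A, RPS19 and RPL35A by 0.32 ± 0.02, 0.33 ± 0.02 and 0.33 ± 0.02, RPS29 by 0.35 ± 0.02 and RPS24 by 0.29 ± 0.02. The others were the translation factors EEF1B2 (0.35 ± 0.02) and EIF3M (0.22 ± 0.02). Ribosomal protein genes have many processed pseudogene copies, and how the authors' counting split such reads is not given in the sources used here. The genes with the lowest correlations were PHF21A (-0.26 ± 0.02), MNDA, a myeloid nuclear antigen (-0.31 ± 0.03), LRP10 (-0.30 ± 0.03), the Fc receptor FCGR2A (-0.41 ± 0.04) and ALOX5, the 5-lipoxygenase of leukotriene synthesis (-0.39 ± 0.04). Libraries with higher ribosomal scores had lower neutrophil scores (r = -0.767, p = 1e-05, rho = -0.786, p = 1e-05, adjusted p = 0.00065 over 325 relations of programme lists; -0.812 and -0.725 within forms; -0.713 without 2 libraries). Both scores are relative within a library, as for the pairs of cell lists. With the neutrophil score as a covariate, the count was 978, of which 894 were among the 3913.

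**Figure D3:**
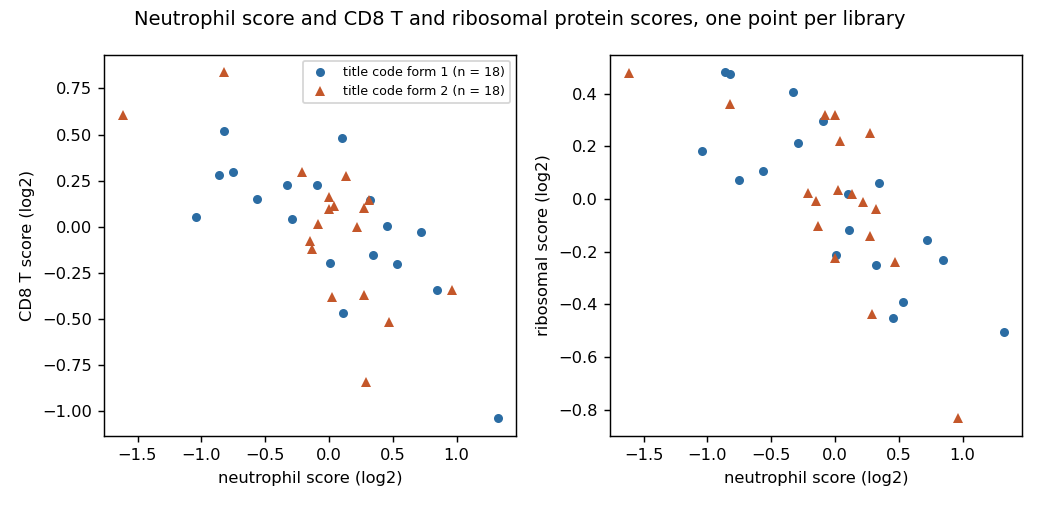
Each point is 1 of 36 libraries, with the neutrophil score on the x axis and the CD8 T score (left) or the ribosomal protein score (right) on the y axis, all in log2 units, and colour and shape give the title code form. Both scores fall as the neutrophil score rises, with r of -0.693 and -0.767.

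With the B cell score, 4005 of 11485 genes changed, 2032 upwards and 1973 downwards. FAM129C (chromosome 19, 17523301 to 17553839) rose by 0.73 ± 0.04 log2 per SD (adjusted p = 5.61e-16). CD72, a B cell coreceptor, rose by 0.62 ± 0.04, SNX22 by 0.55 ± 0.05, GYLTL1B by 0.54 ± 0.06, TNFRSF13C, the receptor for the survival factor BAFF, by 0.45 ± 0.05, the lectin CLEC17A by 0.42 ± 0.04, the signalling adaptor STAP1 by 0.36 ± 0.03, HIP1R by 0.36 ± 0.03, CD40, the receptor for T cell help, by 0.33 ± 0.03 and PARP3 by 0.23 ± 0.03. The lowest correlations were those of CPD (-0.39 ± 0.05), C7orf60 (-0.24 ± 0.03), RYBP (-0.22 ± 0.03), ZMPSTE24 (-0.17 ± 0.03) and SPAST (-0.17 ± 0.03). The count rested in part on few libraries: it was 2127 without replicate 4, and 1300 without the 2 libraries farthest from the median score, of which 1231 were among the 4005. It was 2002, of which 1368 were among the 4005, when each library's trend of values on GC content was removed. The B cell score rose with the library's GC trend (r = 0.534, p = 0.00031, adjusted p = 0.00496 over 32 lists; rho = 0.574, p = 0.00029; 0.447 and 0.665 within forms; 0.506 without 2 libraries). The count was 676 and 1213 in the 2 forms alone.

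With the NK and cytotoxic score, 994 of 11485 genes changed, 488 upwards and 506 downwards. GZMA, the serine protease granzyme A (chromosome 5, 55102648 to 55110252), rose by 0.41 ± 0.04 log2 per SD (adjusted p = 2.85e-10). GPR56, an adhesion receptor, rose by 0.51 ± 0.05, C1orf21 by 0.39 ± 0.04, TTC38 by 0.38 ± 0.04, the kinase MATK by 0.38 ± 0.04, FASLG, the death ligand of cytotoxic cells, by 0.34 ± 0.04, CD247, the zeta chain of the T cell receptor complex, by 0.31 ± 0.03, RUNX3 by 0.31 ± 0.04, SMAD7 by 0.22 ± 0.03 and LPCAT1 by 0.19 ± 0.02. TG (-0.48 ± 0.09), LIMK2 (-0.31 ± 0.06), CDK14 (-0.29 ± 0.05) and the interferon receptor chain IFNAR1 (-0.20 ± 0.04) were among the genes with the lowest correlations. The count was 60 with the neutrophil score as a covariate, all 60 among the 994, with 58 upwards and 2 downwards. It was 532, 648 and 270 without replicates 4, 11 and 27 in turn, 229 without the 2 libraries farthest from the median score, and 48 and 26 in the 2 forms alone. With the GC trend removed it was 1734, of which 921 were among the 994.

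Fewer genes moved with the red cell and platelet scores, and nearly all of them upwards. With the erythroid score, 196 of 11481 genes changed, 189 upwards and 7 downwards, led by SLC6A8, the creatine transporter (chromosome X, 153688099 to 153696593; 0.82 ± 0.06 log2 per SD, adjusted p = 3.53e-14). TMOD1, which caps actin filaments in the red cell skeleton, rose by 0.80 ± 0.06, GMPR by 0.73 ± 0.06, BCL2L1, the anti-apoptotic protein BCL-XL, by 0.65 ± 0.05, NFIX by 0.62 ± 0.05, ANK1, the red cell ankyrin, by 0.61 ± 0.05, MXI1 by 0.58 ± 0.04, IGF2BP2 by 0.54 ± 0.04, TSPAN5 by 0.47 ± 0.04 and RNF10 by 0.38 ± 0.03. The lowest correlations were those of PTPRS (-0.29 ± 0.07), TMIE (-0.25 ± 0.07), HIATL2 (-0.21 ± 0.06), PFAS (-0.13 ± 0.03) and CES2 (-0.11 ± 0.03). With the platelet score, 186 of 11483 genes changed, 173 upwards and 13 downwards. C6orf25, the platelet receptor G6b (chromosome 6, 31718594 to 31726714), rose by 0.57 ± 0.03 (adjusted p = 1.35e-17), ABLIM3 by 0.67 ± 0.05, VSIG2 by 0.64 ± 0.05, the integrin chain ITGB5 by 0.59 ± 0.04, TSPAN9 by 0.59 ± 0.05, the platelet receptor PEAR1 by 0.59 ± 0.04, CTTN, the actin-binding protein cortactin, by 0.57 ± 0.04, the G protein subunit GNAZ by 0.57 ± 0.04, NRGN by 0.56 ± 0.05 and CTDSPL by 0.55 ± 0.04. RXFP2 (-0.44 ± 0.11), PID1 (-0.26 ± 0.06), EFCAB7 (-0.26 ± 0.06), TRPS1 (-0.23 ± 0.05) and PDCD6IP (-0.11 ± 0.03) had the lowest correlations. The platelet count was 95 without the genes in the lowest 25% of mean values and 112 without the 2 libraries farthest from the median score. In forms 1 and 2 alone the erythroid counts were 51 and 148, and the platelet counts 52 and 104.

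With the eosinophil score, 224 of 11490 genes changed, 201 upwards and 23 downwards. SLC29A1, a nucleoside transporter (chromosome 6, 44219505 to 44234151), rose by 0.57 ± 0.04 log2 per SD (adjusted p = 1.49e-12). CYP4F12 rose by 0.60 ± 0.09, CACNG8 by 0.54 ± 0.08, CEBPE, a transcription factor of granulocyte maturation, by 0.46 ± 0.08, SPNS3 by 0.43 ± 0.06, THBS4 by 0.38 ± 0.07, GIPR by 0.37 ± 0.06, POPDC2 by 0.30 ± 0.05, the cannabinoid receptor CNR2 by 0.28 ± 0.05 and SEMA7A by 0.25 ± 0.04. KIAA1161 (-0.25 ± 0.06), FAM105A (-0.21 ± 0.03), ZNF555 (-0.19 ± 0.05), SLC39A11 (-0.16 ± 0.04) and SLC17A5 (-0.12 ± 0.03) had the lowest correlations. The number of called genes was not stable, and 16 of the 36 libraries moved it by more than 1.5 times when left out. It was 45, 58, 100, 106, 109, 135, 137, 139, 142, 143, 144 and 147 without replicates 4, 16, 12, 19, 11, 23, 26, 8, 22, 2, 21 and 28 in turn. It was 382, 392, 546 and 921 without replicates 31, 20, 9 and 24. Without the 2 libraries farthest from the median score, 1826 genes were called, 950 upwards and 876 downwards, and 222 of the 224 were among them. The count was 24 in form 1 alone and 2 in form 2 alone.

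**Figure D4:**
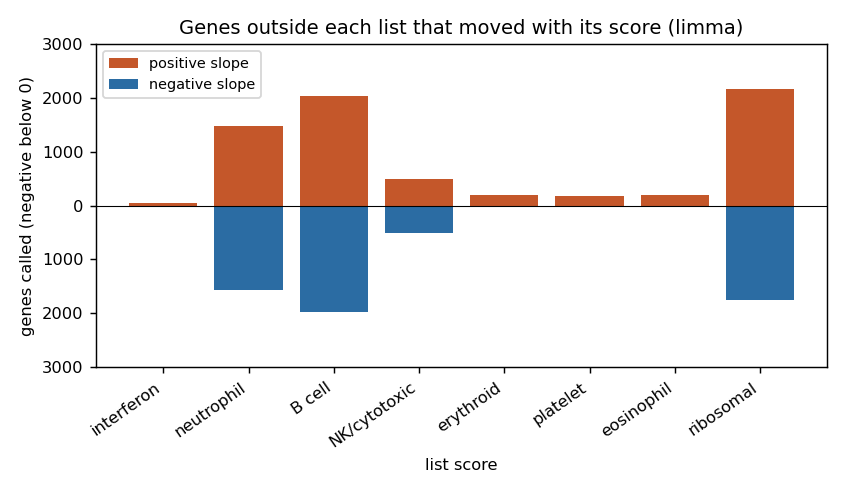
Bars give the number of genes outside each list that changed with its score in 36 libraries (limma, adjusted p under 0.05), upwards for positive slopes and downwards for negative slopes. The counts run from 44 for interferon to 4005 for B cells, and most of the interferon (41 of 44), erythroid (189 of 196), platelet (173 of 186) and eosinophil (201 of 224) genes have positive slopes.

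The most variable genes were taken as the 500 with the largest SD among the 8625 genes above the lowest 25% of mean values. Members of 14 of 32 lists were found there more often than expected (one-sided Fisher's exact test, Benjamini-Hochberg over 32 lists). All 19 eligible erythroid genes were among the 500, where 1.10 were expected (adjusted p = 7.32e-23), as were 18 of 22 interferon genes (3.84e-18), 13 of 17 platelet genes (1.47e-12), 11 of 15 B cell genes (1.97e-10) and 7 of 7 immature granulocyte genes (1.35e-08). Neutrophils had 9 of 14, eosinophils 5 of 5, NK and cytotoxic cells 8 of 16, plasmablasts 4 of 5, basophils 3 of 3, CD8 T cells 3 of 7 and plasmacytoid dendritic cells 2 of 4. NF-kB targets and glucocorticoid-induced genes each had 3 of 9. None of the 40 ribosomal protein, 25 oxidative phosphorylation or 14 T cell genes were among the 500. The gene with the largest SD was HBG2, a fetal globin chain (chromosome 11, 5253190 to 5505605), with a mean of 10.21 ± 2.34 (SD, n = 36), followed by the muscle gene MYOM2 (chromosome 8, 2045040 to 2165552; 8.95 ± 2.05), S100P (10.36 ± 1.96), TMEM176B (10.55 ± 1.66) and TMEM176A (9.30 ± 1.58). Of the 25 genes with the largest SD, 10 belonged to a fixed list: S100P, KRT1 (8.58 ± 1.54), ALOX15, IGJ, LTF, RSAD2, TCL1A, IFI44L, ALAS2 and BPI. The other 15 included the acute phase protein ORM1 (7.66 ± 1.53), COL5A3 (7.66 ± 1.42), the ribosomal protein gene RPS26 (12.13 ± 1.36), KREMEN1 (9.41 ± 1.34) and S100B (7.74 ± 1.29), and FOLR3, ZNF683, CA4, PI3, CNTNAP3 and KIAA1324 with SDs of 1.16 to 1.21. HBG2, ORM1 and the TMEM176 pair have close paralogs, and how the authors' counting split reads between these is not given in the sources used here.

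The last question was which lists the main axes of variation went with. The first 3 principal components of the gene-centred values held 25.6%, 14.0% and 7.88% of the variance, and 24 of 96 relations with list scores passed an adjusted p of 0.05 (permutation test, 100000 permutations). Component 2 rose with the neutrophil score (r = 0.897, rho = 0.873, both p = 1e-05; 0.898 and 0.897 within forms; 0.873 without 2 libraries). It also rose with the score of NF-kB targets (r = 0.779, rho = 0.752, both p = 1e-05; 0.710 and 0.862 within forms; 0.735 without 2 libraries). It went down with the ribosomal score (r = -0.895, rho = -0.894, both p = 1e-05; -0.885 and -0.911 within forms; -0.870 without 2 libraries) and with the CD8 T score (r = -0.753, rho = -0.767, both p = 1e-05; -0.741 and -0.771 within forms; -0.733 without 2 libraries). The adjusted p was 0.000192 for each of these 4 relations. Scores are relative within a library, so opposite directions do not show which of them changed in amount. Of the 9 measured NF-kB targets, 7 rose with the rest of their list over all genes, and TNF and TNFAIP3 did not. Of the lists of RNA quality, the histone score rose with component 2 (r = 0.604, p = 9e-05, adjusted p = 0.00108; rho = 0.511, p = 0.00184; 0.480 and 0.729 within forms; 0.492 without 2 libraries). The heat shock score fell with it (r = -0.418, p = 0.0107, adjusted p = 0.0447; rho = -0.420, p = 0.0108; -0.378 and -0.477 within forms; -0.337 without 2 libraries). T cell (r = -0.685), NK and cytotoxic (-0.612), oxidative phosphorylation (-0.567), MAIT (-0.473), B cell (-0.470) and clock (-0.415) scores also fell with component 2. Their adjusted p lay between 0.000192 and 0.0492. The clock relation was -0.293 without 2 libraries and -0.183 in form 1. B cell, clock and heat shock scores thus passed with component 2 as well as with component 1. Component 1 went with lower clock gene scores (r = -0.686, p = 2e-05, adjusted p = 0.00032; rho = -0.638, p = 3e-05; -0.575 and -0.796 within forms; -0.624 without 2 libraries), lower heat shock scores (r = -0.523, p = 0.00109, adjusted p = 0.00864; rho = -0.475, p = 0.00394; -0.624 and -0.390 within forms; -0.472 without 2 libraries) and higher B cell scores (r = 0.502, p = 0.00126, adjusted p = 0.00864; rho = 0.479, p = 0.00304; 0.516 and 0.489 within forms; 0.563 without 2 libraries). Naive T (r = -0.496, p = 0.0021, adjusted p = 0.0134; rho = -0.478, p = 0.00351; -0.469 without 2 libraries) and non-classical monocyte scores (r = 0.437, p = 0.00747, adjusted p = 0.0341; rho = 0.513, p = 0.00154; 0.370 without 2 libraries) passed as well. Within forms 1 and 2 their r were -0.298 and -0.701, and 0.181 and 0.665, so both were weak in form 1. The clock list was not coherent and 5 of its 11 members rose with the rest over all genes, so its score does not stand for the list as a whole. Of the 10 heat shock members, 7 rose with the rest over all genes, with HSPD1 and DNAJA1 highest. HSPA1A (r = -0.300) and HSPA1B (r = -0.076) did not, so the heat shock score does not stand for these genes. Component 3 went with oxidative phosphorylation (r = 0.644, p = 3e-05, adjusted p = 0.000411; rho = 0.643, p = 4e-05; 0.547 and 0.758 within forms; 0.513 without 2 libraries) and immature granulocyte genes (r = 0.543, p = 0.00067, adjusted p = 0.00585; rho = 0.547, p = 0.00067; 0.515 and 0.567 within forms; 0.462 without 2 libraries). The histone score rose with it too (r = 0.444, p = 0.00681, adjusted p = 0.0327; rho = 0.356, p = 0.0344; 0.491 and 0.413 within forms; 0.369 without 2 libraries). Cell cycle (r = 0.520), erythroid (0.483), progenitor (0.467) and B cell (-0.431) scores also passed with component 3, with adjusted p between 0.00864 and 0.0367. The progenitor relation was 0.214 without 2 libraries and the B cell relation -0.299 in form 2. By rank, the B cell relation had a rho of -0.260 (permutation p = 0.123).

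Component 1 also followed the base composition of genes. Across 11453 genes, which are not independent replicates, the correlation of a gene with component 1 rose with the GC content of its longest transcript (Spearman rho = 0.713). Across libraries, component 1 rose with each library's GC trend, the Spearman rho between GC content and the deviation of genes from their means, which ran from -0.590 to 0.636 (r = 0.945, rho = 0.930, both p = 1e-05; 0.961 and 0.928 within forms; 0.935 without the 2 libraries farthest on component 1). Both measures are made from the same gene deviations. This r therefore restates in large part the relation across genes, and its p is not separate evidence. Besides the B cell score, the clock score was the only 1 of 32 list scores to pass with the GC trend (r = -0.588, p = 0.00016, adjusted p = 0.00496; rho = -0.559, p = 0.0006; -0.550 and -0.633 within forms; -0.517 without 2 libraries). For components 2 and 3 the rho across genes were -0.149 and -0.165. With each library's GC trend removed, 28 relations passed, and components of the same rank are then not the same axes. The largest component then went with T cell (r = -0.799) and ribosomal (-0.769) scores and with clock scores (-0.766), while its r with the B cell score was -0.084 (adjusted p = 0.775).

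**Figure D5:**
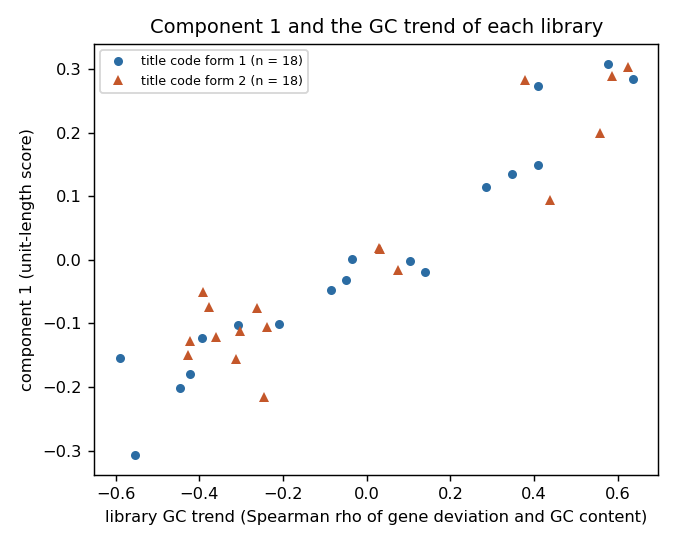
Each point is 1 of 36 libraries, with its GC trend (Spearman rho across 11453 genes) on the x axis and its unit-length score on component 1 on the y axis, and colour and shape give the title code form. Component 1 rises with the GC trend, with r of 0.945, and both measures are made from the same gene deviations.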

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

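The GC and length alternatives, the fits without the 2 libraries farthest from a score and those with 1 library left out were chosen after the data were seen, and the others before. No alternative other than those on GC content and length turned the direction of a called component relation, and none turned that of a called score pair, of a list's median r where it had been called, or of a named gene that had passed. Outside the fits with 1 library left out, 80 counts under an alternative stayed within 1.5 times of the reported one and 40 did not. Of single lists, pairs, relations and genes, 2215 values kept their side of the threshold or their size, 233 no longer passed, 19 newly passed and 8 turned direction, while 27 counts of named genes that passed changed. These numbers leave out the removal of title code form means and the comparison of the forms, whose outcome the equal gene means fix. They still count the form as a covariate, although equal gene means leave every slope unchanged there. That setting called no new gene for any score, so its unchanged values are no sign of stability. The counts of coherent lists (22 to 32) and component relations (21 to 28) stayed within 1.5 times throughout. The component relations themselves changed more than their count. With the GC trend removed, 13 of the 28 were among the 24 called in the values as deposited. With GC and length trends removed, 11 of 23 were. Each title code form has fewer samples than the whole. The depth of single libraries is unknown, so no limit from depth can be given. No paired analysis was possible because the series has 1 group.

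Called score pairs numbered 15, and 5 without the 2 libraries least like the others, 0 and 2 in title code forms 1 and 2, and 6 with GC content and length trends removed, all of these among the 15. In form 1 alone, genes called numbered 12 with the interferon score, 1257 with neutrophil, 676 with B cell, 48 with NK, 51 with erythroid, 52 with platelet, 24 with eosinophil and 1737 with ribosomal; in form 2 alone, 14 (interferon), 1222 (neutrophil), 1213 (B cell), 26 (NK), 104 (platelet), 2 (eosinophil) and 1766 (ribosomal). With the neutrophil score as a covariate the counts were 75 (interferon), 60 (NK), 422 (eosinophil) and 978 (ribosomal). Without the 2 libraries least like the others they were 577 (NK), 123 (platelet) and 40 (eosinophil), and without the 2 farthest from the score 26 (interferon), 1300 (B cell), 229 (NK), 112 (platelet) and 1826 (eosinophil). With the GC trend removed they were 2002 (B cell) and 1734 (NK), and with GC and length trends removed 1889 (B cell), 1937 (NK) and 344 (eosinophil). Without the lowest 25% of genes they were 95 (platelet) and 1598 (eosinophil, with 5 members left in its list), and with z-scores 126 (eosinophil). With the GC trend removed, component 1 had r of -0.084 with the B cell score, and component 2 of 0.020 with heat shock and 0.125 with clock genes. With GC and length trends removed, component 1 had r of -0.169 with B cells and -0.022 with non-classical monocytes, and component 2 of 0.085 with T cells, 0.434 with heat shock (adjusted p = 0.0347, the 1 of these 8 that passed) and 0.051 with clock genes. All 8 had the opposite sign in the values as deposited; the GC trend correlated with component 1 (r = 0.945), so after its removal components of the same rank are other axes, and these signs do not compare like with like. With 200 variable genes, 9 lists were enriched in place of 14. The cause of these changes was not tested, also where an alternative had fewer samples or genes.

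With 1 library left out, the counts ran from 37 to 50 (interferon), 2519 to 3285 (neutrophil), 2127 to 4429 (B cell), 270 to 1305 (NK), 167 to 203 (erythroid), 127 to 237 (platelet), 45 to 921 (eosinophil) and 3477 to 4202 (ribosomal).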

Other observations

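Tests on component 1 with GC content, length and the B cell score, those on extreme libraries, on globin values and on splits of the libraries were chosen after the result was seen. Those on the B cell markers lowest in GC content and on the GC trend in the cell cycle relation were chosen before. The test on the B cell score was added once that on the markers had left the question open. Cell cycle and plasmablast genes rose together, the strongest relation between a programme and a cell list after that of NF-kB targets with neutrophils among the 325 relations between programme lists and all lists. The cell cycle score rose with the plasmablast score (r = 0.791, p = 1e-05, adjusted p = 0.00065; rho = 0.728, p = 1e-05; 0.828 and 0.681 within title code forms). TNFRSF17, the plasma cell receptor BCMA, had an SD of 1.15 log2 over the 36 libraries and CDC20, a mitotic checkpoint protein, one of 0.93. The NF-kB score rose with the neutrophil score (r = 0.828, p = 1e-05, adjusted p = 0.00065; rho = 0.832, p = 1e-05; 0.837 and 0.819 within forms; 0.823 without 2 libraries). Of the 9 measured NF-kB targets, 7 rose with the rest of their list over all genes, with PLAUR and IL1B highest. TNF (r = 0.157) and TNFAIP3 (r = 0.038) did not, so the score does not stand for NF-kB targets as a whole. The 2 interferon lists rose together (r = 0.676, p = 2e-05, adjusted p = 0.000929; rho = 0.602, p = 0.00014; 0.590 and 0.795 within forms; 0.666 without 2 libraries).

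Among lists of sample handling and RNA quality, the immediate early score was lower where the naive T score was higher (r = -0.549, p = 0.00054, adjusted p = 0.00877; rho = -0.658, p = 2e-05; -0.355 and -0.781 within forms; -0.649 without 2 libraries). Of the 14 immediate early genes, 1 rose with the rest of the list over all genes and 10 when adjusted over the list alone. Their median pairwise r was 0.175, so this score is a mean of genes that moved little together. The score of replication-dependent histone genes rose with the neutrophil score (r = 0.656, p = 4e-05, adjusted p = 0.00144; rho = 0.630, p = 9e-05; 0.556 and 0.782 within forms; 0.577 without 2 libraries). The clock score rose with the T cell score over all libraries (r = 0.583, p = 0.00019, adjusted p = 0.00433; rho = 0.510, p = 0.00182; 0.523 without 2 libraries), but r was 0.039 in form 1 and 0.836 in form 2, so the relation does not hold within both forms. The clock list was not coherent (adjusted p = 0.0651), so its score does not stand for the list as a whole.

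Component 1, the widest axis of these values, went with clock, heat shock and B cell scores, less so in form 1 with naive T and non-classical monocyte scores, and divided genes by base composition. B cell abundance as its whole cause would need a B cell score close to the component, and r was 0.502 (95% bootstrap interval 0.233 to 0.690). GC content bias between libraries may account for much of it: rho across genes with GC content was 0.713, a spline on GC content held 14.0% of all variance, and with that trend removed the largest component held 17.8%. Transcript length may add to it, with a partial rho of -0.368 given GC content. For the B cell markers alone the 2 readings cannot be told apart, since the 8 markers lowest in GC content had a median r of 0.222 with component 1, between the bounds set in advance, and the other 8 one of 0.613.

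The relation of cell cycle and plasmablast scores did not come from a few extreme libraries, since r was 0.641 without the 2 libraries farthest from the median cell cycle score. A GC content bias between libraries did not account for it either, with r of 0.788 once each library's GC trend was removed. No biological explanation was tested, because the labels give 1 group.

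HBB, the gene with the highest mean, had 2 distinct values over 36 libraries, which is consistent with the authors' normalization fixing the value of the top rank. Among red cell genes, HBD and ALAS2 had 36 distinct values each, with SDs of 0.97 and 1.15. HBA2 also had 2 distinct values and HBA1 had 5, so spreads of these 3 genes between the libraries are not read from the deposited values.

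For the title code forms, 100 splits of the libraries into 18 and 18 were counted, the real one included. The real split gave 0 genes, which the equal gene means fix and every split reaches, so whether chance can be excluded cannot be read from them. Of the other splits, 97 gave 0 genes as well, and the highest gave 1797. That split was drawn at random, so its genes were called for a grouping with no meaning of its own. Genes that move together can thus be called together in large number, a limit that the gene counts of the scores share. The B cell score had an r of 0.502 with component 1. The split with 1797 genes had the largest r of the splits with component 1, 0.483 in size. The splits next to it on that component, with r of 0.395 and 0.384 in size, gave 0 genes past the threshold. At an unadjusted p under 0.05 they gave 2532 and 1849, against a median of 352 over the splits other than the real one. Splits with r of 0.467 and 0.428 in size with component 2 gave 1959 and 2001. High unadjusted counts thus went with splits that followed component 1 or 2. What lies behind these components cannot be read from the splits. At an unadjusted p under 0.05 the real split gave 0 genes and the others between 66 and 4215.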
